A study of Mus musculus with 4 samples.

How the data were processed

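ChIP-seq was performed on hearts dissected from mouse embryos at embryonic day 9.5 that carried a Hopx allele with a triple Flag tag. Per the labels' protocols, pooled hearts were fixed in 1% formaldehyde for 10 min, in 1 of the 2 experiments together with EGS, the chromatin was sonicated, and 10 µg was used for each pull-down with an anti-Flag antibody. The labels' protocols also name mouse IgG as a negative control; an IgG library was not analysed here. Each experiment had an anti-Flag library and an input library, giving 4 libraries in 4 groups of 1. Samples were grouped by their titles.

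Per the submitters' processing notes, Bowtie 0.12.7 and HOMER were used with the mouse build mm9. Per the series' design text, background noise was subtracted before analysis. The HOMER version, the peak calling settings, the threshold and the overlap rule for merging are not given in the sources used here. The authors deposited 1 list of merged regions for the series, in BED form with no header. Its columns give the chromosome, start, end, name, score and strand of each region. The deposited score is 1 in every row and carries no height, enrichment or p-value, and every row has the same strand, so neither column was used. Start positions count from 0 in the deposited list and are given here counted from 1. The list ran past the last gene of the gene table supplied (assembly GRCm38.p6) on 6 chromosomes, by 6.95 Mb on chromosome 7. A region can lie past the last gene of its own assembly, so this alone does not settle the build. The build was taken as mm9 from the submitters' notes. That table was therefore used only for this check.

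No read counts or depths stand behind the regions in the deposited list, so precision could be given only for counts of regions: exact 95% intervals (Clopper-Pearson for shares, Poisson for counts, and the conditional binomial for ratios of densities), all of which cover counting error only. With 1 library per group and 1 merged list, no test between crosslinking conditions was possible, and no region was traced to a library. The number at the end of each region name was read as the count of merged peaks, which was checked against the widths.

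The following was computed from the list, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Clustering was measured as the number of neighbouring regions with centres under 10 kb apart and compared with 1000 random placements between the first and last region of each chromosome (two-sided permutation test). Chance overlap was estimated by placing 2 equal lists at random over the same spans 1000 times. A local version, added after the data were seen, moved every peak by up to 10 kb 1000 times, with the 2 peaks of a merged region in different lists and the others in a list at random. The equal split gives about the most chance overlaps that lists of this total size can have. Blocks were made by joining regions with edges within 10 kb. Blocks with a region merged from 2 peaks were compared with as many blocks hit by regions drawn at random (10000 draws), also without the chromosome 9 block whose values had prompted the comparison. Densities used the span from the first to the last region of each chromosome, since no mm9 chromosome lengths were at hand. Dense blocks on X and Y were compared with those on the autosomes by Fisher's exact test. The spread over autosomes was tested against 10000 random draws in proportion to span, and single autosomes with exact binomial tests, with Benjamini-Hochberg adjustment and a threshold of 0.05.

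The clustering test and the regions to be named were fixed before the data were examined, as were the alternatives of overlap by 50%, distances of 5 and 50 kb, merging within 1 kb for the number of regions and the spread, and leaving out the densest chromosome. All other alternatives were added after the data were seen. The rule named the 10 regions with the highest score, the 5 widest regions and the 5 densest 100 kb windows. The first part could not be applied, since the score is constant, and ties between windows went to the lower chromosome number. In the placements that moved regions by up to 1 Mb, positions past the first or last region were reflected back, a detail set after the data were seen. The tests of spread over span, of block positions and of chromosomes X and Y were added after the data were seen. The clustering test was tested on simulated lists of 3775 regions: it called 0 of 20 random lists, and 20 of 20 lists to which 100 close regions had been added, with a median excess of 95.4 pairs. Planned comparisons with transcription start sites, fixed gene lists and sequence motifs were not run, because no genome or annotation of mm9 was used here, and the planned comparison of score with width was not run because the score is constant.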

Results

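Chromatin bound by Hopx was profiled in the hearts of mouse embryos at embryonic day 9.5 by chromatin immunoprecipitation and sequencing (ChIP-seq). Hopx is a small homeodomain protein that does not itself bind DNA and reaches chromatin through partner proteins. The embryos carried 1 Hopx allele fused to a triple Flag tag, so that an anti-Flag antibody (M2) pulled down the tagged protein with its DNA. The series held 4 libraries, 1 in each of 4 groups. There was an anti-Flag library and an input library from chromatin fixed with formaldehyde alone, and another such set from chromatin fixed with formaldehyde and EGS, a long-armed crosslinker that joins protein to protein. The question the design poses is where in the genome Hopx sits in the early heart, and whether the added crosslinker captures it. The groups had no replicates, so the 2 crosslinking conditions could not be tested against each other.

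The deposited result was a single list of merged binding regions for the whole series. It held 3775 regions on 21 chromosomes (the 19 autosomes, X and Y) and covered 760.1 kb in all. Of these, 3730 regions were 201 bp wide and 45 were wider, up to 390 bp, and no region overlapped another. The score was 1 in every row, so the list ranked no region above another and gave neither height nor enrichment over input. The sequencing depth behind the regions is unknown, since the list carries no read counts. No gene, promoter or sequence motif was assigned to a region, because no annotation or sequence of the build mm9 was used here. Regions are therefore named by position.

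Few of the regions were merged from more than 1 peak, as read from their names. Each region name ends in a number, 1 for 3720 regions and 2 for 55. All 45 regions wider than 201 bp were among the 55, and none of the 3720 was wider, as regions made from 2 partly overlapping peaks would be. The number is therefore read as the count of peaks merged into a region, although the list does not define it or say which immunoprecipitation each peak came from. The regions merged from 2 peaks made up 1.46% of the list (exact 95% interval 1.10 to 1.89%, for counting error only). When 2 lists of equal size, with 3830 peaks in total, were placed at random along the chromosomes, 0.676 overlaps arose on average and at most 4 in 1000 placements, against the 55 observed. Such placement ignores the dense places in the list. When every peak was instead moved by up to 10 kb, 10.1 overlaps arose on average and at most 22 in 1000 placements. Moves of that size keep the dense places only coarsely, since they spread out blocks of a few kb.

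The regions merged from 2 peaks were gathered in a few places. Chromosome 9 held 28 of the 55, and 23 of those lay between positions 3000007 and 3038297, the proximal end of the assembled chromosome. A block on chromosome 2 from 98502397 to 98507356 held 5 regions, all 5 merged from 2 peaks, and another on that chromosome from 147191586 to 147194305 held 3, again all merged. These last blocks were picked out after their values were seen, and whether any of these places holds repeated sequence was not examined here. With regions within 10 kb of each other counted as 1 block, the 55 regions fell into 24 of 3521 blocks, or 0.682% (exact 95% interval 0.437 to 1.01%). A block with 2 or more regions merged from 2 peaks occurred 6 times, and these blocks together held 37 of the 55 regions. The other 18 blocks held 1 such region each, and in 13 of them it stood without a neighbour.

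Compared with regions from 1 peak, regions merged from 2 peaks had close neighbours more often. Another region lay within 10 kb of 42 of the 55 (76.4%, exact 95% interval 63.0 to 86.8%) and of 333 of the 3720 (8.95%, 8.05 to 9.92%). Regions of 1 block are not independent, and the test therefore took blocks as the unit. Larger blocks have more chances to hold a region merged from 2 peaks, so the background was the blocks hit by regions drawn at random. Of the 24 blocks with a region merged from 2 peaks, 11 held more than 1 region, against a mean of 2.38 and at most 9 in 10000 draws (permutation test, two-sided, adjusted p = 0.0003, Benjamini-Hochberg over 3 tests, from the smallest p that these draws can give). Without the chromosome 9 block, 10 of 23 did, against a mean of 2.16 and at most 8 (permutation test, adjusted p = 0.0003). In the first 200 kb after position 3 Mb, where mouse chromosome assemblies begin beside the centromere, lay 24 of the 55 regions merged from 2 peaks and 25 of the 3720 others, and 23 of the 24 belonged to the chromosome 9 block. Without that block, 1 of 23 blocks lay there against a mean of 0.138 in the draws, 7.22 times as many, and this single block did not pass the threshold (permutation test, adjusted p = 0.263).

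The 5 widest regions were all merged from 2 peaks. The widest, 390 bp, lay on chromosome 7 from 6190160 to 6190549. If each parent peak was 201 bp wide, the parents shared 12 bp there. The next were 373 bp on chromosome 18 (35015874 to 35016246), 328 bp on chromosome 7 (28198150 to 28198477), 309 bp on chromosome 4 (80479991 to 80480299) and 272 bp on chromosome 9 (35112815 to 35113086). Under the same assumption, 51 of the 55 regions came from peaks that shared at least 50% of their length, and 10 from peaks at the same position.

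Regions lay closer together than random placement would put them. There were 251 pairs of neighbouring regions with centres under 10 kb apart, against a mean of 63.6 (central 95% 50 to 78) in 1000 placements between the first and last region of each chromosome, a ratio of 3.95 (two-sided permutation test, p = 0.002, the smallest that 1000 placements can give). At a limit of 5 kb the ratio was 5.84, with 188 pairs observed and 32.2 expected, and at 50 kb it was 1.64, with 487 observed and 296.5 expected. Most regions still stood alone: 3396 of the 3521 blocks held a single region, 85 held 2, 24 held 3 or 4, and 16 held 5 or more.

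**Figure D1:**
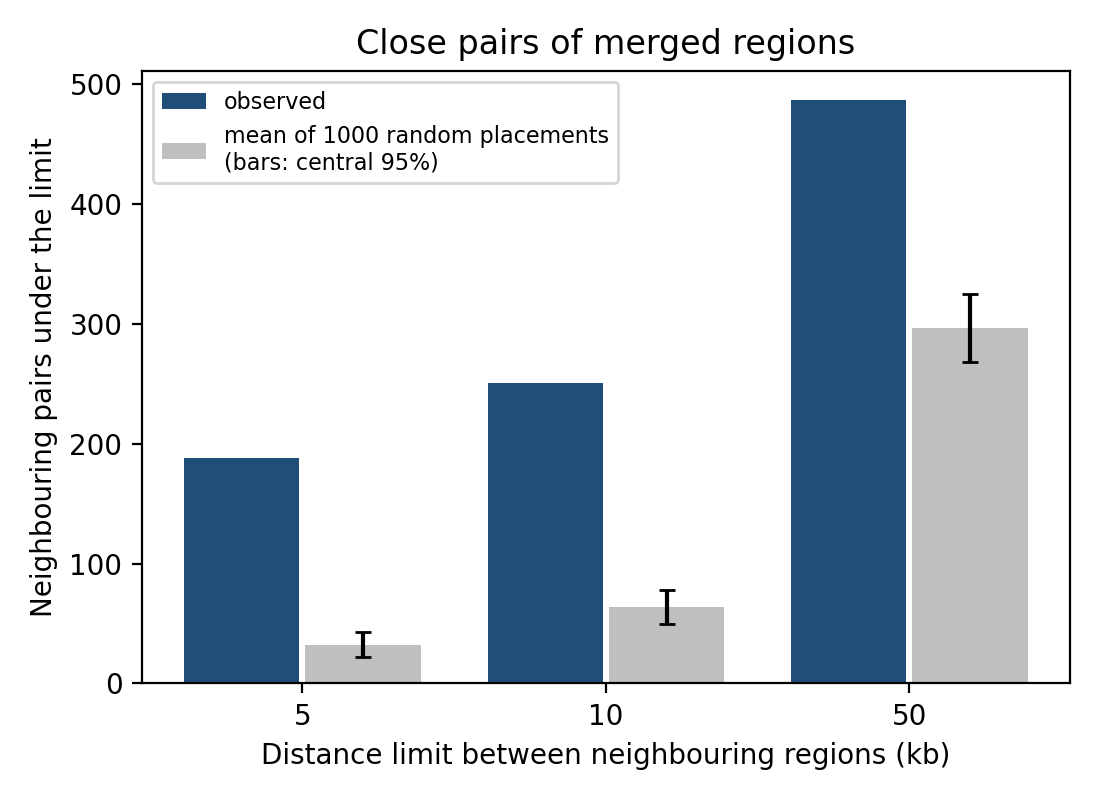
Number of neighbouring pairs of merged regions (vertical axis) whose centres lie under 5, 10 or 50 kb apart (horizontal axis), observed (dark bars) and as the mean of 1000 random placements within the span of each chromosome (grey bars, error bars the central 95%). The observed counts of 188, 251 and 487 all lie above the range of the placements.

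The densest 100 kb window lay at the proximal end of chromosome 9, where 26 regions stood within 38.3 kb (exact 95% Poisson interval of the count 17.0 to 38.1). The interval does not allow for the window having been picked as the densest. The mean over all chromosomes was 0.148 regions per 100 kb. Of these 26 regions 23 were merged from 2 peaks. The next windows lay on the sex chromosomes and held only regions from 1 peak. On chromosome X there were 20 regions from 121210495 to 121308360 and 12 from 120112473 to 120129365, where the chromosome's own mean was 0.0630 per 100 kb. On chromosome Y there were 10 regions from 2779838 to 2877219, where the chromosome's mean was already 2.26 per 100 kb. The last of the 5 windows, with 7 regions, lay on chromosome 5 from 14907553 to 15007408. Ties were broken by chromosome order, and blocks on chromosomes 17 and X also held 7 regions. These 5 windows held 75 regions, 1.99% of the list, and 41.8% of the regions merged from 2 peaks.

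**Figure D2:**
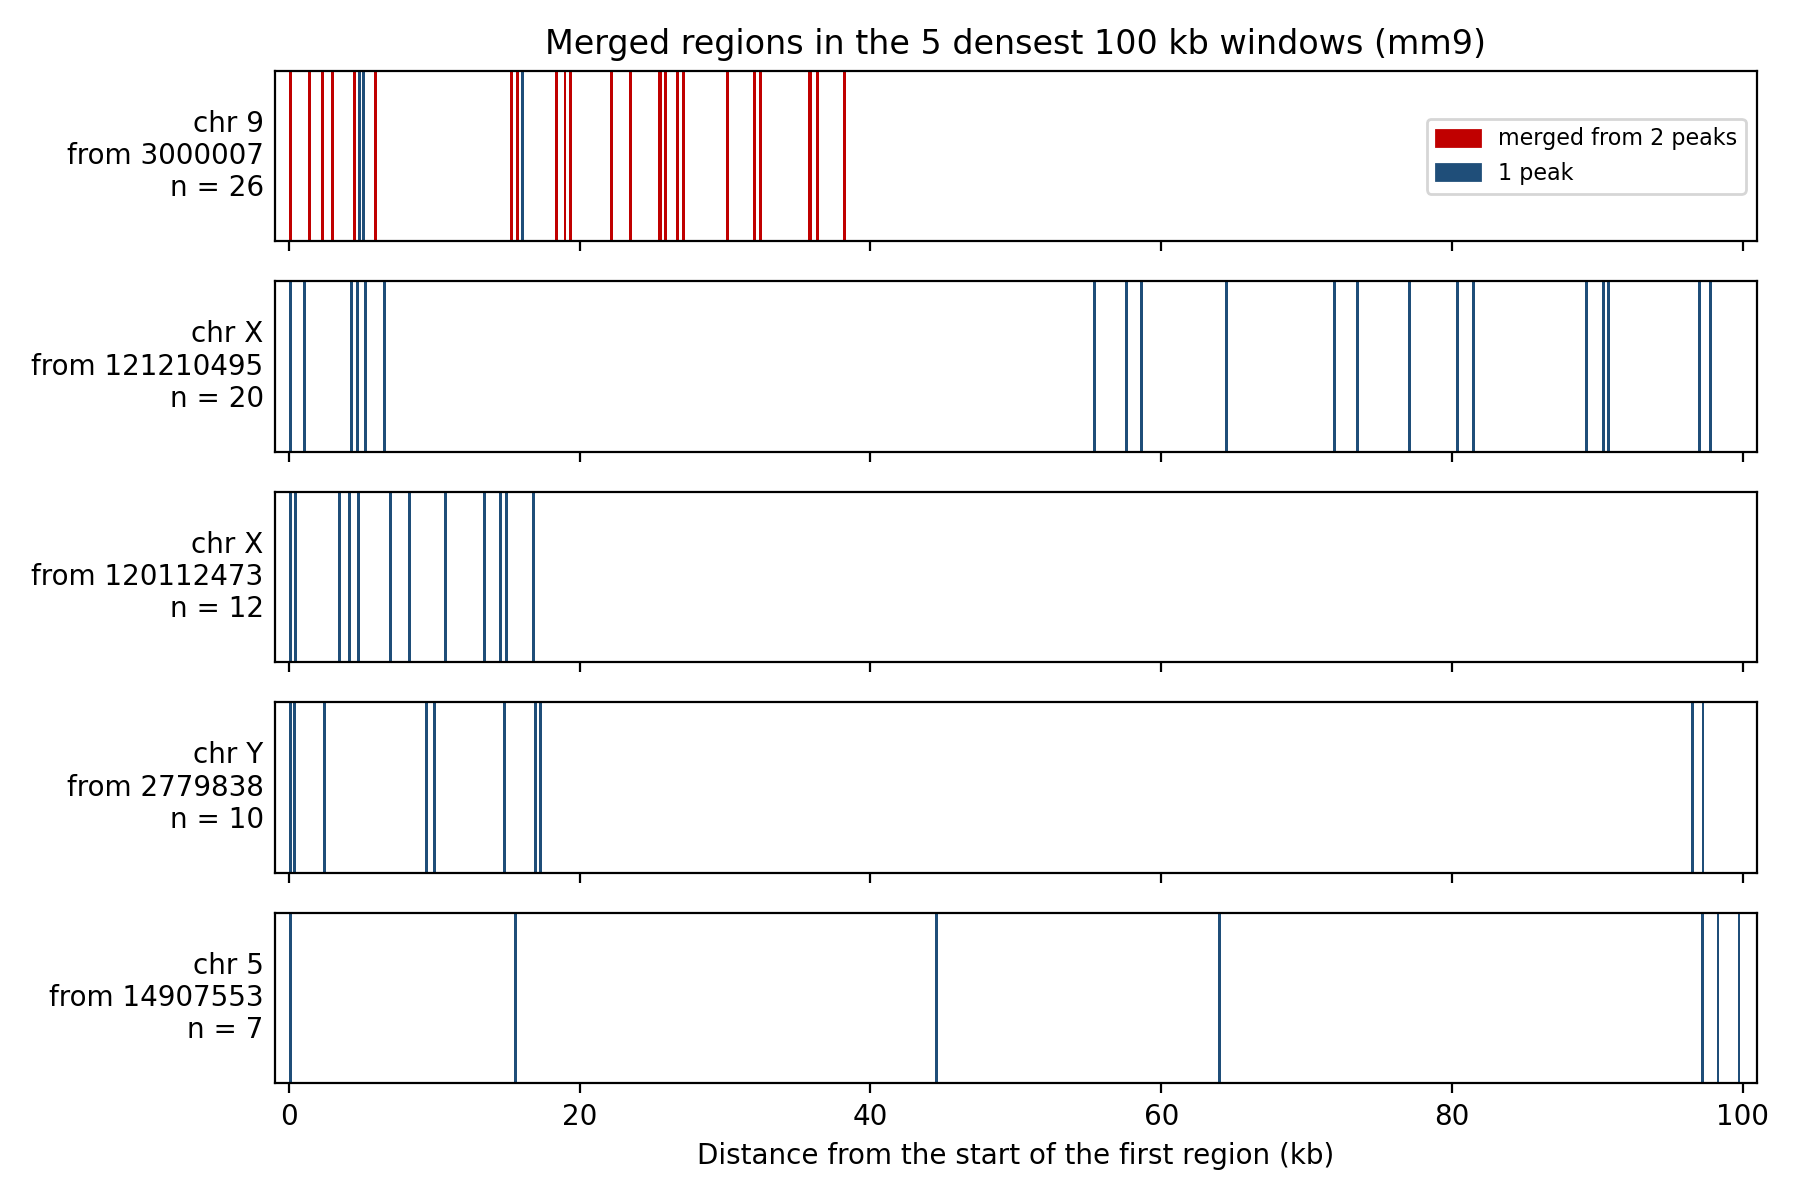
Positions of the merged regions in the 5 densest 100 kb windows, drawn to scale, with the distance from the start of the first region in kb on the horizontal axis; each row gives the chromosome, the position of its first region in mm9 and the number of regions. Regions merged from 2 peaks (red) appear in the chromosome 9 window, where they are 23 of 26, and the windows on X, Y and 5 hold only regions from 1 peak (blue).

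Across the autosomes the density of regions was fairly even, with a mean of 1.52 regions per Mb of the sequence between the first and last region of each chromosome. It ranged from 1.19 per Mb on chromosome 15 (exact 95% Poisson interval 0.987 to 1.43) to 1.91 per Mb on chromosome 9 (1.67 to 2.18), a 1.60-fold range. This spread was larger than chance placement in proportion to span would give (chi-square 56.0 against a mean of 18.1 in 10000 random draws, permutation test, p = 0.0001, the smallest that these draws can give). Chromosome 11 held 222 regions where 181 were expected (exact binomial test, two-sided, adjusted p = 0.0244 over 19 chromosomes), and chromosome 9 held 231 where 184 were expected (adjusted p = 0.0108). Chromosome 15 held 117 where 149 were expected (exact binomial test, adjusted p = 0.0367). With regions within 10 kb counted once, chromosome 11 still stood above its expected number (1.26-fold, exact binomial test, adjusted p = 0.0146), whereas chromosome 9 (1.15-fold, adjusted p = 0.228) and chromosome 15 (0.809-fold, adjusted p = 0.175) no longer passed. Spans include unassembled gaps, which could not be removed.

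Chromosome X held fewer regions for its length than the autosomes, and the regions on chromosome Y all lay within a span of 1.64 Mb. Chromosome X held 102 regions over 161.9 Mb, 0.630 per Mb, which was 0.413 times the autosomal density (exact 95% interval 0.336 to 0.503). Of these, 47 lay in a stretch of 1.20 Mb from 120112473 to 121315694, and the rest of the chromosome had 0.342 regions per Mb. With regions within 10 kb counted once, X fell to 0.187 times the autosomal density (0.136 to 0.252). Chromosome Y held 37 regions over 1.64 Mb, between positions 1266095 and 2901779. Its 22.6 regions per Mb were 14.8 times the autosomal density (10.4 to 20.5), or 6.32 times with regions within 10 kb counted once (3.53 to 10.4). These ratios depend on the span, which the regions on Y themselves set. A length of 2.90 Mb, from position 1 to the last region, was chosen after the data were seen. Over it the ratios were 8.37 (5.88 to 11.6) and 3.56 (1.99 to 5.88). The length of Y in mm9 was not used here. Whether the short span reflects the assembled sequence of Y or the placement of the regions therefore cannot be told.

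Dense blocks held a larger share of the regions on the sex chromosomes. Blocks of 5 or more regions made up 6 of 44 blocks on X and 3 of 15 on Y, against 7 of 3462 on the autosomes (Fisher's exact test, two-sided, adjusted p = 8.84e-09 for X and 7.66e-06 for Y, over 2 tests). Blocks close to each other are not independent, and 5 of the 6 on X lay in the stretch from 120112473 to 121315694 and 2 of the 3 on Y between 2779838 and 2901779. Without these stretches, 1 of 38 blocks on X and 1 of 13 on Y held 5 or more regions, and neither chromosome passed the threshold (Fisher's exact test, adjusted p = 0.0837 for X and 0.0591 for Y). The stretches were picked for the dense blocks they held, so leaving them out lowers these counts by construction. With all blocks counted, those of 5 or more held 52.0% of the regions on X, 48.6% on Y and 1.68% on the autosomes. The autosomal blocks of this size lay on chromosomes 2, 4, 9, 17 and 18. Of the 55 regions merged from 2 peaks, 2 lay on X and 0 on Y. The intervals of these densities cover counting error only, and all values come from 1 merged list.

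**Figure D3:**
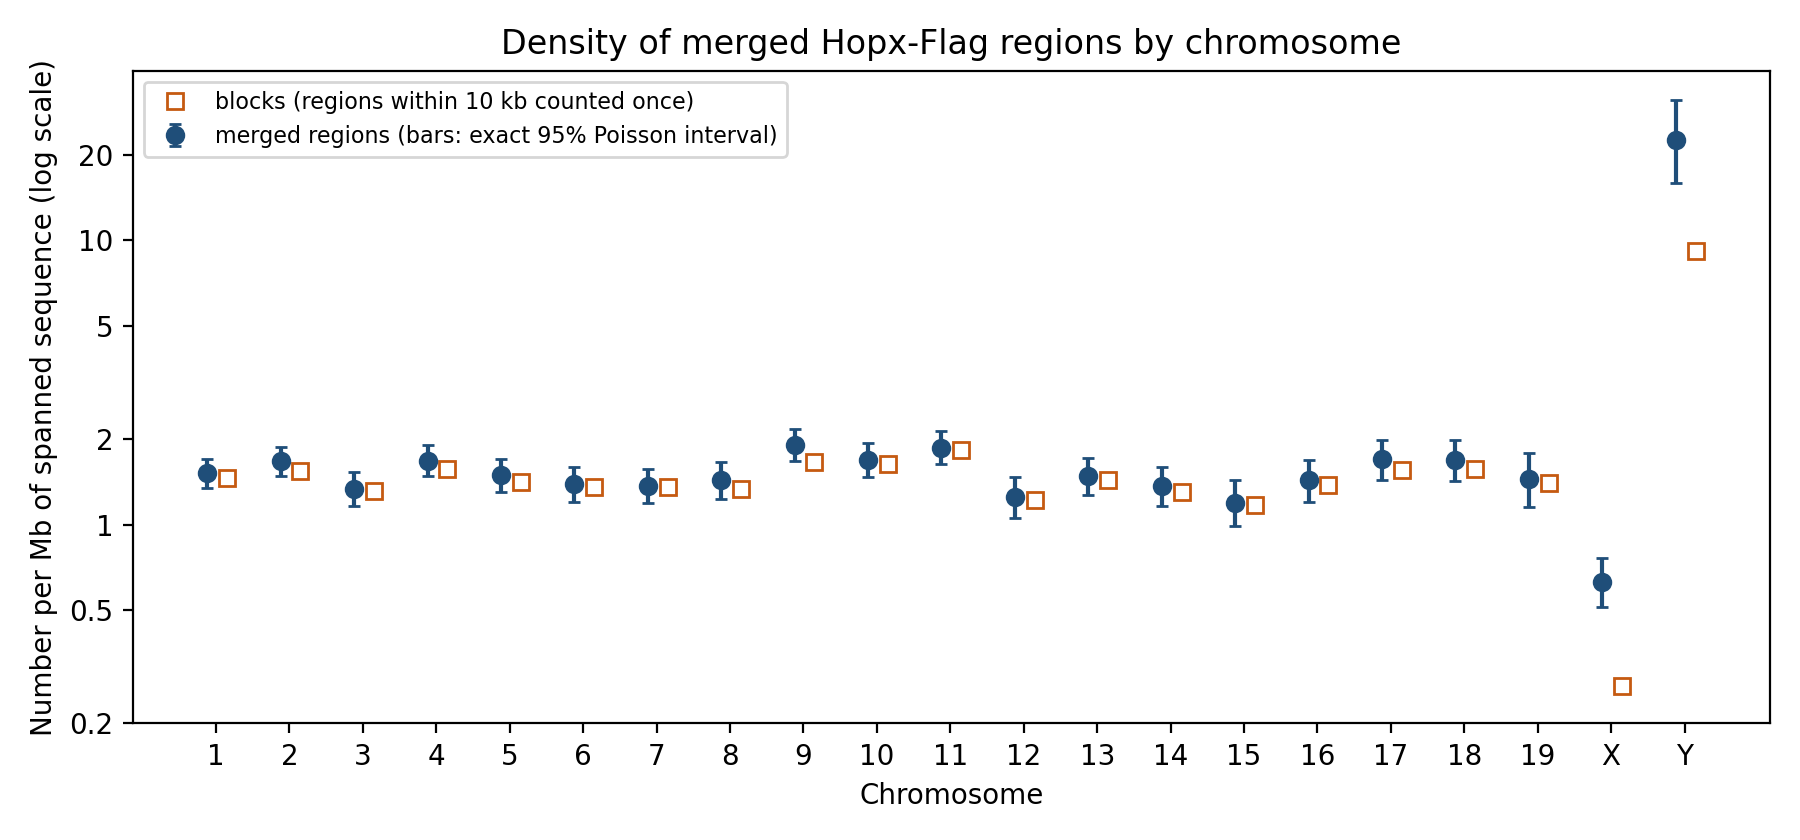
Number of merged regions per Mb between the first and last region of each chromosome (filled points, bars the exact 95% Poisson interval) and the same with regions within 10 kb counted once (open squares), on a log axis, for chromosomes 1 to 19, X and Y. The autosomes lie between 1.19 and 1.91 regions per Mb, X at 0.630 and Y at 22.6, over a span of 1.64 Mb that its own regions set.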

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

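The number of regions (3775) moved little when regions within 1 kb (3681) or, as added after the data were seen, within 10 kb (3521) were counted once. The share of regions merged from 2 peaks was 1.46% and stayed inside its counting interval when an overlap of at least 50% of a 201 bp peak was required (1.35%). It fell to 0.682% with regions within 10 kb counted as 1 block and to 0.865% without the 5 densest 100 kb windows, both chosen after the data were seen. The fall follows from the construction in both, since blocks with several such regions, the largest with 23 at the proximal end of chromosome 9, are counted once or, for that block, left out. The ratio of close pairs to random placements (3.95) kept its direction and p = 0.002 (permutation test) under all 7 alternatives run, from 1.64 at 50 kb to 5.84 at 5 kb. It was 4.05 without chromosome Y, and under settings added after the data were seen 2.69 with regions merged within 1 kb, 3.46 without the regions merged from 2 peaks, 3.15 without the 5 densest windows and 2.93 against regions moved by up to 1 Mb. The uneven spread over autosomes held with regions within 1 kb (chi-square 46.4, p = 0.0005) or, as added after the data were seen, within 10 kb (39.2, p = 0.0016) counted once. Alternatives that need a score, an mm9 genome or an mm9 annotation were not run. No paired analysis was possible because each group has 1 library and the list is not divided by library. Depth is unknown, so whether the low share of regions merged from 2 peaks reflects a shallow library cannot be judged from the list.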

Other observations

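The proximal chromosome ends held 49 regions, in 11 blocks on 9 chromosomes, in the first 200 kb after 3 Mb, 8.27 times the 5.92 expected at the mean density. Most of this excess came from chromosome 9. Without that chromosome 23 regions remained, 4.09 times the number expected when it is left out of the expectation as well. These 23 formed 10 blocks, 1.81 times the 5.51 expected at the autosomal density of blocks, with an exact 95% Poisson interval of 0.870 to 3.34 that includes 1, so that no excess of places was shown there. Chromosomes 4 and 17 held 6 regions each there, from 3009436 to 3018700 and from 3077834 to 3084563, none merged from 2 peaks. Chromosome 12 held a single region, merged from 2 peaks, from 3109929 to 3110132. At the distal end of chromosome 2, a block of 6 regions lay from 181652087 to 181665565, and 1 of them was merged from 2 peaks. Away from the ends, a block of 7 regions lay on chromosome 17 from 13735875 to 13745992, and a block of 5 on chromosome 18 from 35015874 to 35023809, of which 1 was merged from 2 peaks. These places were picked out after their values were seen.

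All tests in the next paragraphs were added after the data were seen. For the test of blocks on chromosome Y and both tests of close pairs, the value they measure was not yet known. The 55 regions merged from 2 peaks exceed the at most 4 that random placement gave, which ignores the dense places. They also exceed the at most 22 when every peak was moved by up to 10 kb. Such moves spread out blocks of a few kb, so chance overlap within those blocks cannot be excluded. Dense blocks alone do not account for all 55, since 11 of them had no other region within 100 kb. These 11 alone exceed the at most 4 from random placement, which argues against chance overlap of evenly placed peaks as the whole cause. Even placement does not allow for differences in mappable sequence. Signal piled up on repeated sequence, which is common beside mouse centromeres, is a candidate explanation for the 43.6% of the 55 that lay in the first 200 kb after 3 Mb. The exact 95% interval of that share (30.3 to 57.7%) counts regions as independent, although 23 of those there lay in 1 block. This explanation stays open there, and equally for the chromosome 2 block from 98502397 to 98507356, since no sequence or repeat annotation of mm9 was used here. So does binding of Hopx found in both preparations, which was not tested.

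Copy number may be set against the densities of the sex chromosomes. Chromosome Y is present once in male cells only, yet its density over the span of its regions was 14.8 times the autosomal one, and 6.32 times with regions within 10 kb counted once. Neither value excludes copy number or local clusters, because the span is set by the regions themselves: the bound fixed for the blocks before the result was seen overlooked this. The interval of the ratio would reach 0.5 at a mappable length of Y of 34.1 Mb. At any shorter length it would lie above 0.5, higher than 1 copy in male cells would give. The interval of the blocks would reach 1 at 5.78 Mb. Which of these cases holds is not known, since the length of Y in mm9 was not used here. For X, the ratio of 0.413 had an interval that reached 0.503, just past the 0.5 of a sample with male embryos only. That is the lowest value in proportion to copies, and a pool that also held female embryos would lie above it. The ratio of 0.413 was raised by 1 stretch of 1.20 Mb that held 47 of the 102 regions. Elsewhere X had 0.342 regions per Mb, against 1.52 on the autosomes. The blocks gave a lower ratio of 0.187, with an interval (0.136 to 0.252) wholly below 0.5. Copy number on X stays open, because peaks called against a threshold need not fall in proportion to copies and the sexes of the pooled embryos are not given in the sources used here. Reads from unassembled copies of repeated sequence on Y, and a preference of Hopx for some sequences, were not tested.

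The closeness of regions was not the work of the 5 densest windows alone. Without these windows the ratio to random placement fell from 3.95 to 3.15 (185 pairs against 58.8, p = 0.002, permutation test). Differences in mappable sequence on scales well above 1 Mb did not account for all of the closeness. Against regions moved at random by up to 1 Mb the ratio was 2.93 (251 pairs against 85.6, at most 115 in 1000 placements). Such moves also smooth out differences on smaller scales. Uneven mappable sequence on those scales, repeats on a scale of a few kb and groups of nearby binding sites therefore all stay open. None of them could be tested without sequence.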
